A study of Mus musculus with 6 samples.

How the data were processed

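Poly(A)-selected RNA, from DNase-treated total RNA of testes of C57BL/6 mice aged 8 months, was sequenced in 6 libraries, 3 labelled control and 3 labelled L3mbtl2 conditional knockout (cKO), per the labels. L3MBTL2 is a malignant brain tumour domain protein and a subunit of the Polycomb repressive complex PRC1.6. The labels name neither the deleter strain nor the cell type in which the gene was deleted. Libraries were grouped by the genotype label, and each is called here "the library labelled" control or cKO with its replicate number, because the targeted gene was higher under the label cKO. The names of the deposited tables carry the opposite genotype from the titles and genotype labels of the samples they belong to. Groups followed the labels, as fixed before the data were examined. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be partly technical.

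The deposited tables give, per the file headers, a gene identifier, its transcripts, a length, an expected count, an FPKM value, a symbol, ontology terms and descriptions for each gene. Expected counts and FPKM are columns that RSEM writes, and RSEM is named in the submitters' processing notes. These also name bcl2fastq 2.16, HISAT2 2.0.4, Bowtie2 2.2.5, DESeq2 and the mouse build mm10, with no role or order for any tool. The length differs between libraries for genes with several isoforms, as RSEM's abundance-weighted transcript length does. Expected counts in the deposited tables are not normalized: 24.6 to 25.8% of them were not whole numbers, and they summed to between 17689205 and 18822050 per library. FPKM is scaled by the authors for length and depth. Only genes with an FPKM of at least 0.01 are listed in each table, so a gene missing from a table was set to 0. In all, 23253 genes were listed in any library and 19702 in all 6 libraries. Of these, 21118 carry an Entrez identifier and 21071 were matched to a RefSeq gene table of assembly GRCm38.p6, the same primary assembly as mm10, which gave chromosomes and coordinates. The remaining 2135 are transcript models assembled by the submitters' pipeline, which held 2.26 to 2.75% of the expected counts. They have no symbol or position here. No mitochondrially encoded gene is listed. Strandedness of the libraries is not given in the sources used here, so overlapping antisense genes, and families of near-identical genes such as Tuba3a with Tuba3b or the alpha globins, are uncertain.

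Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 18269 genes. Library sizes were scaled by TMM, and the labelled cKO group was compared with the labelled control group by the quasi-likelihood F-test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are given throughout as labelled cKO minus labelled control. FPKM values are shown as mean ± SD over 3 libraries and were not used in the main test. With these totals, counting error in well-read genes was small beside the spread between libraries, which had a common biological coefficient of variation of 22.8%. For genes near the minimum count of 10 it was not small. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p below 0.1.

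A set of 21 gene lists was fixed before the data were examined: 13 of cell types that a testis or tissue dissected with it can hold, and 8 of complexes and pathways. X-linked and Y-linked genes were 2 further sets. Each was tested with camera in limma 3.58.1 on log2 CPM (counts scaled to a common library size; prior count 2), with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 sets that had at least 3 measured genes. The epididymis list, with 1 measured gene, was left out of that test. Camera with a correlation estimated per list and fry were run beside it. The genes the text names were chosen by a rule fixed in advance: L3mbtl2, then up to 8 genes in each direction with the largest change past the threshold, an FPKM of at least 1 in the higher group, no overlap between groups and a symbol that is not a clone or predicted-gene name, and then for each list its 3 members with the smallest adjusted p or, where no member passed, its 2 most abundant members by FPKM. Because no gene passed in edgeR, the middle part of the rule named no gene, and 42 genes were named in all. Any other gene in the text was chosen after its values were seen.

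The alternatives were DESeq2 size factors in edgeR, library totals alone, DESeq2 1.42.0 with its own defaults, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in at least 3 libraries, no filter on low counts, a stricter filter of 5 CPM in at least 3 libraries, leaving out each library in turn, the replicate number as a block, and camera with an estimated correlation. In 1 further alternative, chosen after seeing the data, the mean log2 CPM of the Sertoli and Leydig lists entered the model as a covariate. This score was higher in every library labelled control than in any labelled cKO, so such fits can absorb a group difference of any cause. Gene ontology terms, as the deposited tables assign them, were tested on the genes called by DESeq2 with a one-sided Fisher exact test in scipy 1.17.1, for terms with 10 to 500 genes among the genes that DESeq2 tested and that carry a term.

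The steps were tested on simulated data first. Counts for the 18269 genes were drawn from the real means, library sizes and gene-wise dispersions, with 100 well-read genes changed 2-fold and 100 changed 4-fold. edgeR recovered 54% of the 2-fold and 95% of the 4-fold changes, with 20 false calls. DESeq2 recovered 72% and 97%, with 62 false calls, and limma, run there on log2(CPM + 1), 54% and 96%, with 18 false calls. With much smaller dispersions, edgeR recovered 97% and 100%. Camera called a shifted list and did not call an unshifted one. Genes were drawn independently there, whereas the correlation estimated in the real libraries was 0.90 for the Sertoli list and 0.92 for elongating spermatids. That check therefore cannot show that the preset correlation of 0.01 limits false calls in the real lists. The ontology test found a planted term, and found 0 terms in a random set of the same size.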

Results

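Messenger RNA was measured in 6 testis libraries from mice aged 8 months. Of these, 3 are labelled control and 3 are labelled L3mbtl2 cKO, and the design compares the groups to ask how loss of L3mbtl2 alters the testicular transcriptome. The deposited expected counts summed to 18040325, 18083291 and 17689205 in the libraries labelled control and to 18822050, 18782063 and 18604191 in those labelled cKO. The 10 most abundant genes took 2.59 to 3.17% of the counts. The most abundant gene was the protamine Prm2 in every library except that labelled control replicate 3, where it was Insl3, a peptide hormone of Leydig cells.

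The targeted gene was examined first, and it was higher, not lower, in the libraries labelled cKO. L3mbtl2 (Entrez 214669, mm10 chromosome 15, 81663889 to 81688315, 5 transcripts in the deposited tables) had 658, 705 and 673 expected counts in the libraries labelled control and 1030, 1105 and 1031 in those labelled cKO. The means were 679 ± 24.0 and 1055 ± 43.0 (SD, n = 3 each), and the TMM-scaled level in the libraries labelled control was 62.7% of that in the libraries labelled cKO. The log2 fold change was 0.67 (SE 0.10), with all 3 libraries labelled cKO above all 3 labelled control. An exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 allows. In edgeR's quasi-likelihood test the gene ranked 6 of 18269 with an adjusted p of 0.166. DESeq2 gave an adjusted p of 0.000497, and edgeR gave 0.00848 without the library labelled control replicate 2; over all alternatives the adjusted p ran from 0.000497 to 0.669. FPKM differed less, at 14.2 ± 0.660 against 16.3 ± 0.663 (log2 difference of FPKM + 1, 0.19), and the length by which FPKM is scaled also differed, at 2717 ± 106 bases against 3493 ± 4.83 bases. Every direction given here is drawn by the labels and would turn if they were exchanged.

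**Figure D1:**
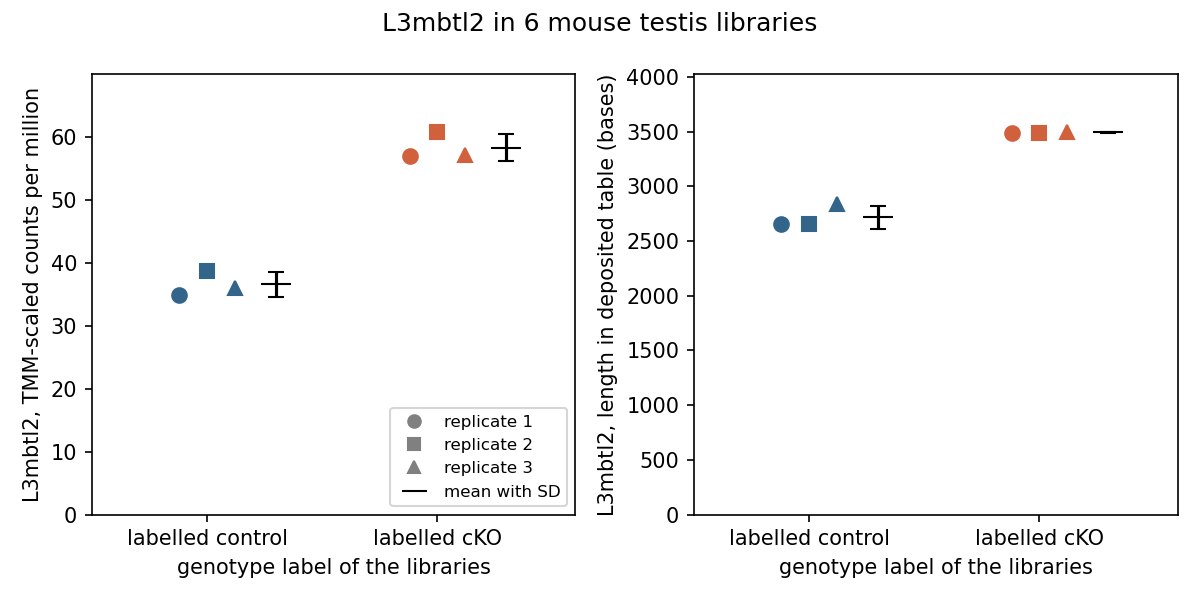
L3mbtl2 in each library, grouped by genotype label, as TMM-scaled CPM (left) and as the length in bases that the deposited table assigns to the gene (right). Points are libraries, and the bar beside them is the mean with its SD (n = 3). The libraries labelled control lie at 35.0 to 38.8 CPM and those labelled cKO at 57.0 to 60.9, so the gene is lower where the label says control.

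Gene by gene, no change passed in the main test. edgeR's quasi-likelihood test called 0 genes higher and 0 lower of 18269 at an adjusted p of 0.05, with a lowest adjusted p of 0.166. At an unadjusted p of 0.05, 1617 genes were higher and 3439 lower in the libraries labelled cKO, and 37.9% of genes had no overlap between the groups. Chance gives 10% on average over splits of the libraries, but genes move together, so a single split can lie far from it. The share was not computed for other splits. DESeq2 called 72 genes higher and 1364 lower of 17789, and limma on FPKM called 1 higher (BGI_novel_G001288, an assembled model chosen after its values were seen) and 0 lower. A single library decided the edgeR count: without the library labelled control replicate 2, edgeR called 2049 genes higher and 3851 lower, and 1430 of the 1436 genes that DESeq2 called were among them, all with the same sign. The libraries labelled control differed from each other far more than those labelled cKO did. Their pairwise correlations of log2 CPM across genes were 0.937 to 0.972, against 0.981 to 0.982 among the libraries labelled cKO. The library labelled control replicate 2 correlated at 0.980 to 0.982 with those labelled cKO. With control replicates 1 and 3 it correlated less, at 0.972 and 0.937. Leaving it out thus removes the library labelled control that is most like those labelled cKO. The mean log2 CPM of the Sertoli and Leydig markers was 6.11, 5.39 and 6.99 in the libraries labelled control and 5.01, 5.01 and 4.90 in those labelled cKO.

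Markers of the somatic cells that nourish germ cells and make testosterone were lower in the libraries labelled cKO. The Leydig list, which holds steroidogenic enzymes and hormones of the interstitial cells, had a median log2 fold change of -1.83, a 3.55-fold difference, and all 18 measured members were negative. Insl3 stood at 3840.3 ± 3122 FPKM in the libraries labelled control and 1022 ± 79.8 in those labelled cKO (log2 -1.80, SE 0.52), and the prostaglandin D synthase gene Ptgds at 744 ± 453 against 238 ± 37.8 (log2 -1.54, SE 0.38; SD, n = 3 each). In the Sertoli list, the supporting cells of the tubule, all 25 members were negative with a median of -1.004. Clu, encoding the secreted chaperone clusterin, stood at 929.6 ± 489 against 399.8 ± 9.26 FPKM (log2 -1.11, SE 0.32), and the cystatin gene Cst12 at 201 ± 99.2 against 93.4 ± 3.28 (log2 -1.004, SE 0.29). Camera with the preset correlation gave adjusted p of 3.3e-07 for the Leydig and 2.5e-08 for the Sertoli list, and neither call held with an estimated correlation (adjusted p = 0.562 for each). Over all genes tested edgeR called 0 members of either list, but adjusted over the list alone 18 of 18 Leydig and 24 of 25 Sertoli genes were lower. DESeq2 called 10 and 21 of them lower, Ptgds, Clu and Cst12 included. Without the library labelled control replicate 3 the medians were -0.999 and -0.59, still past the preset threshold. These directions follow labels that L3mbtl2 leaves in doubt.

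**Figure D2:**
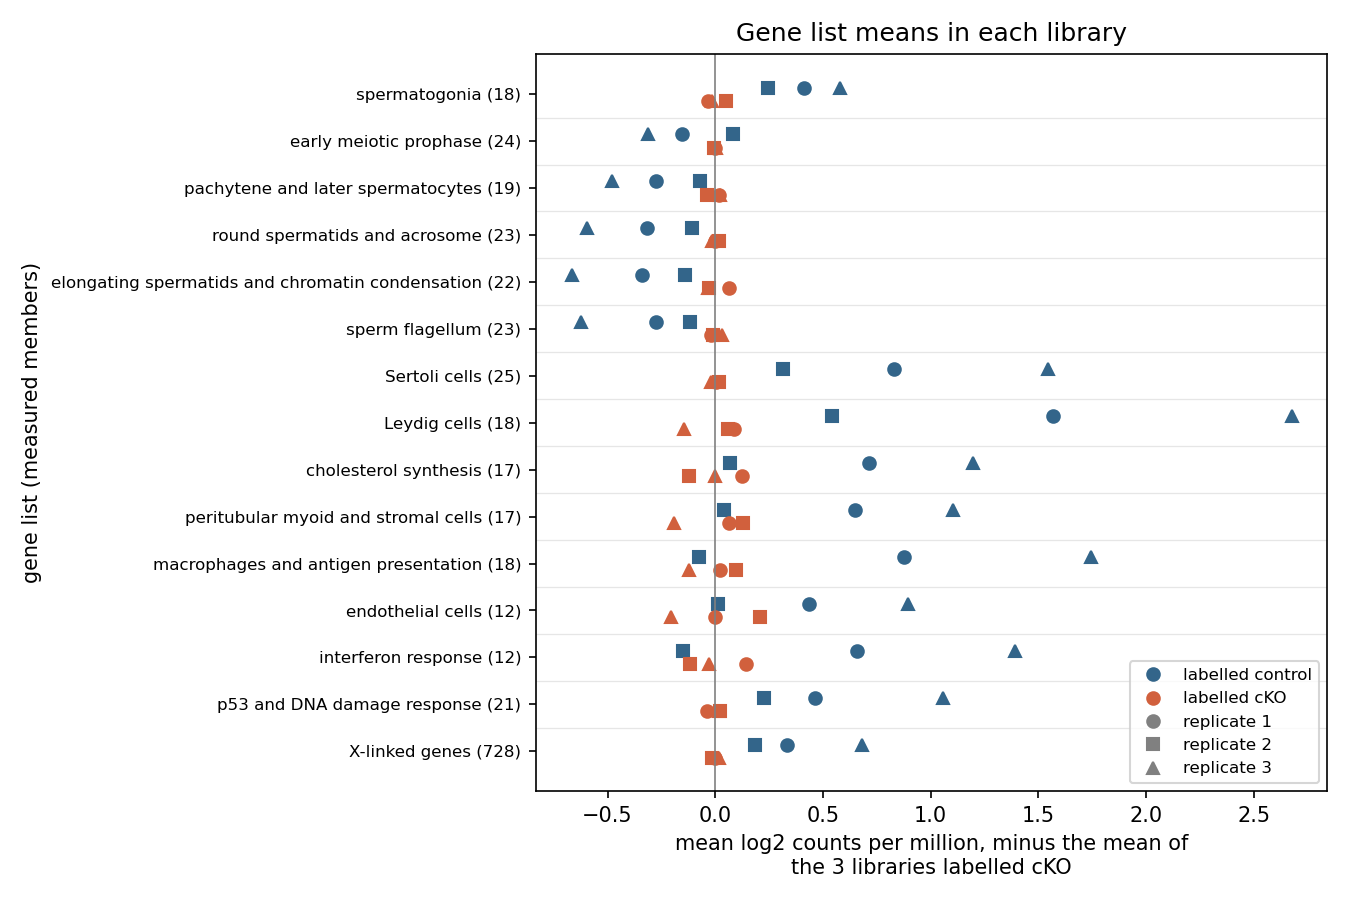
Mean log2 CPM of each gene list in each library, minus the mean of the 3 libraries labelled cKO; measured members are in parentheses, points are libraries and shapes are replicate numbers. The Leydig list spans 0.54 to 2.68 above that mean in the libraries labelled control, while the round spermatid list spans -0.60 to -0.11.

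Lists of other cells of the interstitium and tubule wall had lower medians too in the libraries labelled cKO, by labels that L3mbtl2 leaves in doubt. Macrophage and antigen presentation genes had a median of -0.97 with all 18 members negative (camera adjusted p = 0.000557; adjusted p = 0.562 with an estimated correlation). Lysozyme Lyz2 stood at 49.99 ± 37.3 FPKM in the libraries labelled control against 17.3 ± 1.62, and Cd74, the MHC class II invariant chain, at 23.6 ± 17.4 against 13.8 ± 2.54. Peritubular myoid and stromal genes had a median of -0.71 (15 of 17 negative, camera adjusted p = 0.00279; adjusted p = 0.562 with an estimated correlation). The myosin light chain Myl9 was at 55.9 ± 21.2 against 29.95 ± 4.28 FPKM, whereas the smooth muscle actin Actg2 lay the other way, at 149.7 ± 20.4 against 177 ± 4.15. Endothelial genes had a median of -0.56 (11 of 12 negative, camera adjusted p = 0.0102; adjusted p = 0.562 with an estimated correlation); the tight junction gene Cldn5 was at 7.69 ± 2.24 against 4.94 ± 0.519, and Egfl7 at 3.83 ± 0.251 against 3.56 ± 1.03 FPKM (log2 0.024 by TMM but -0.076 by library totals). For these 3 lists edgeR called 0 members over all genes or adjusted over the list alone. DESeq2 called 6 macrophage genes lower (Csf1r, Cd68, Cd163, C1qa, C1qc and Fcer1g), and 5 myoid and stromal genes (Myh11, Myl9, Col4a1, Pdgfra and Igf1). Without the library labelled control replicate 3 the endothelial list no longer passed (adjusted p = 0.106, median -0.31), nor did it without the library labelled cKO replicate 3 (0.0687) or on FPKM (0.0729 and 0.0736); over its alternatives the adjusted p ran from 0.00226 to 0.562. The macrophage and myoid medians without the library labelled control replicate 3 were -0.41 and -0.42. The difference rests on the libraries labelled control replicates 1 and 3: in replicate 2 the mean log2 CPM of the macrophage, myoid and endothelial lists, minus the mean of the libraries labelled cKO, was -0.075, 0.040 and 0.013. With the somatic score as a covariate, chosen after seeing the data, the macrophage, myoid and endothelial medians turned to 0.55, 0.22 and 0.12.

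Lists of lymphocytes and blood cells did not pass. Lymphocyte genes, 6 of 16 measured, had a median of -0.064 (adjusted p = 0.998), with the T-cell receptor subunit Cd3d at 1.98 ± 0.417 against 2.30 ± 0.390 FPKM and Cd8b1 at 1.21 ± 0.235 against 1.26 ± 0.144. Blood cell genes, 5 of 9 measured, also had a median of -0.064 (adjusted p = 0.998), where camera's direction was up and so differed in sign from the median, which was 0.26 in DESeq2. The globins Hbb-b1 and Hba-a1 stood at 25.9 ± 5.52 against 23.1 ± 17.6 and 17.6 ± 2.43 against 26.8 ± 13.0 FPKM. Of 15 epididymis genes only Rnase10 was measured, at 0.807 ± 0.760 against 1.75 ± 1.499 FPKM, and that list was not tested.

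Transcripts of haploid germ cells were higher in the libraries labelled cKO, by a smaller and more uniform margin, and again by labels that L3mbtl2 leaves in doubt. Elongating spermatid genes, which encode the proteins that pack sperm chromatin and build the tail, had a median log2 fold change of 0.36, a 1.29-fold difference, with 22 of 22 members positive. Prm1 and Prm2, neighbouring genes on mm10 chromosome 16 (10796332 to 10796823 and 10791377 to 10792105), stood at 6402 ± 1179.5 against 7818 ± 406 and 6372 ± 1127 against 7692 ± 457 FPKM (SD, n = 3 each). Round spermatid and acrosome genes had a median of 0.34 with 23 of 23 positive; Actl7b, a testis actin-like gene, was at 328 ± 53.5 against 392 ± 23.2, and the spermatid kinase Tssk2 at 290.1 ± 34.3 against 354 ± 9.33 FPKM. Sperm flagellum genes had a median of 0.33 with 23 of 23 positive. The outer dense fibre genes Odf1 and Odf2 were at 972 ± 150.4 against 1177 ± 37.3 and 1422 ± 199 against 1716 ± 16.4. Camera's adjusted p with the preset correlation was 2.6e-07, 6.3e-07 and 8.0e-07 for these lists, and adjusted p = 0.562 with an estimated correlation for each. No member passed in edgeR over all genes or adjusted over the list alone, and DESeq2 called Catsper3, a sperm calcium channel gene, in the round spermatid list. Without the library labelled control replicate 3 the medians were 0.24, 0.22 and 0.20, and those calls held with the preset correlation. With the somatic score as a covariate, chosen after seeing the data, the medians were 0.0086, -0.018 and -0.029, and none of the 3 lists passed (adjusted p = 0.915, 0.626 and 0.293).

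Earlier germ cells divided by stage. Pachytene and later spermatocyte genes had a median of 0.31 (17 of 19 positive, camera adjusted p = 0.000182; adjusted p = 0.562 with an estimated correlation). The germ cell glycolytic enzymes Ldhc and Pgk2 were at 1856 ± 266 against 2139 ± 47.7 and 493 ± 75.7 against 584 ± 19.4 FPKM. Early meiotic prophase genes had a median of 0.15 (19 of 24 positive, adjusted p = 0.0227; adjusted p = 0.701 with an estimated correlation), with the synaptonemal complex genes Syce1 at 166 ± 24.9 against 196 ± 1.154 and Syce2 at 117 ± 14.1 against 136 ± 7.99 FPKM. The pachytene median was 0.18 without the library labelled control replicate 3. The early meiotic list no longer passed without the library labelled control replicate 1 (adjusted p = 0.054) or replicate 3 (0.214, median 0.072), on FPKM (0.0616 and 0.0725) or with the strict filter (0.0589), while its median was 0.34 without replicate 2 and 0.049 by library totals; its adjusted p ran from 6.88e-05, in the fit with the somatic score as a covariate, where the median turned to -0.15, to 0.701. In that fit, chosen after seeing the data, the pachytene median was -0.039 (adjusted p = 0.392) and the spermatogonial one -0.14 (0.00881). Spermatogonial genes went the other way, with a median of -0.44 (14 of 18 negative, adjusted p = 0.00279; adjusted p = 0.562 with an estimated correlation). The deubiquitinase Uchl1 was at 46.3 ± 8.33 against 32.2 ± 2.45 FPKM, and Id4, a marker of undifferentiated spermatogonia, at 18.6 ± 1.30 against 19.3 ± 0.725. For these 3 lists edgeR called 0 members over all genes or adjusted over the list alone. DESeq2 called Pou5f2 higher in the pachytene list and Kit, Dmrt1 and Foxo1 lower in the spermatogonial list; Kit, the stem cell factor receptor, is also made by Leydig cells. All these directions follow labels that L3mbtl2 leaves in doubt.

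Of 4 lists of germline pathways and of the PRC1.6 complex, 2 passed with the preset correlation, both higher in the libraries labelled cKO. The piRNA pathway, which silences transposons in germ cells, had a median of 0.24 (16 of 17 positive, camera adjusted p = 0.00118; adjusted p = 0.562 with an estimated correlation); Mael was at 615 ± 81.8 against 707 ± 35.5 and Gtsf1 at 263 ± 38.4 against 304 ± 8.81 FPKM. Histone removal and ubiquitination genes of spermatids had a median of 0.19 (16 of 17 positive, adjusted p = 0.00327; adjusted p = 0.562 with an estimated correlation), with Phf7 at 869 ± 122.7 against 1059 ± 13.4 and the histone H3.3 gene H3f3b at 193 ± 7.77 against 201 ± 10.8. The piRNA median was 0.40 without the library labelled control replicate 2, 0.14 without replicate 3 and 0.15 by library totals; that of histone removal was 0.093 by library totals and 0.069 and 0.071 on FPKM. Of the 18 piRNA genes, 7 are also in another list. The PRC1.6 complex list did not pass: its median was -0.14 (12 of 15 negative, adjusted p = 0.449), or -0.084 without the library labelled control replicate 3, -0.24 by library totals and -0.23 and -0.24 on FPKM. L3mbtl2 itself was its 1 member to pass adjusted over the list alone, Hdac1 was at 74.7 ± 8.22 against 84.9 ± 2.21 and Cbx3 at 28.9 ± 5.09 against 24.3 ± 0.373 FPKM. Germline genes that PRC1.6 occupies in embryonic stem cells, 14 of 22 of them also in another list, had a median of 0.16 (16 of 22 positive, adjusted p = 0.151); the near-identical tubulins Tuba3a and Tuba3b were at 708 ± 124 against 817 ± 16.2 and 731 ± 128.5 against 833 ± 19.8. That list passed without the library labelled control replicate 2 (adjusted p = 0.00841, median 0.31) and in DESeq2 (0.0481), while its median was 0.072 (0.721) without replicate 3 and 0.059 by library totals; its adjusted p ran from 3.71e-07, in the fit with the somatic score as a covariate, where the median turned to -0.17, to 0.748. In that fit, chosen after seeing the data, the piRNA median turned to -0.11 and that of histone removal was 0.0056 (adjusted p = 0.915).

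Stress and metabolic lists were lower in the libraries labelled cKO, by labels that L3mbtl2 leaves in doubt. Genes of the p53 and DNA damage response had a median of -0.60 (19 of 21 negative, camera adjusted p = 0.000700; adjusted p = 0.562 with an estimated correlation). The stress sensor Sesn2 was at 17.3 ± 5.41 against 10.6 ± 0.357 FPKM, while Mdm2, the ligase that degrades p53, was at 51.7 ± 3.49 against 53.7 ± 0.326, and DESeq2 called Trp53inp1, Ccng1, Sesn1, Gadd45a and Phlda3 lower. Cholesterol synthesis genes had a median of -0.84 (14 of 17 negative, adjusted p = 0.00759; adjusted p = 0.562 with an estimated correlation), and 9 of them were lower adjusted over the list alone. Fdps was at 83.5 ± 25.0 against 59.6 ± 4.15 and Fdft1 at 102 ± 6.55 against 113 ± 0.796 FPKM. Interferon response genes had a median of -0.85 (12 of 12 negative, adjusted p = 0.00856; adjusted p = 0.562 with an estimated correlation), with Bst2, which tethers virus particles to the cell, at 10.3 ± 5.73 against 4.65 ± 0.399 FPKM. Without the library labelled control replicate 3 the medians were -0.29, -0.42 and -0.31, and the cholesterol and interferon lists no longer passed (adjusted p = 0.054 and 0.228); the interferon list also failed on FPKM (0.0801 and 0.0962) and with the strict filter (0.113). Over the alternatives their adjusted p ran from 6.28e-05 and 5.6e-05, in that order, to 0.562. In the library labelled control replicate 2 the mean log2 CPM of the cholesterol and interferon lists, minus the mean of the libraries labelled cKO, was 0.067 and -0.15, so that difference rests on replicates 1 and 3. In the fit with the somatic score as a covariate, chosen after seeing the data, the p53, cholesterol and interferon medians turned to 0.051, 0.14 and 0.30.

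X-linked genes were lower in the libraries labelled cKO, by the labels. Over 728 X-linked genes the median log2 fold change was -0.45, with 503 negative and 225 positive (camera adjusted p = 8.0e-07; adjusted p = 0.562 with an estimated correlation; fry adjusted p = 0.189). The set's mean log2 CPM were 2.98, 2.83 and 3.32 in the libraries labelled control and 2.64, 2.62 and 2.66 in those labelled cKO. The median was -0.28 without the library labelled control replicate 3 and -0.046 with the somatic score as a covariate (adjusted p = 0.0891), and the adjusted p ran from 6.23e-08 to 0.562 over the alternatives. DESeq2 called 141 X-linked genes lower and 3 higher (Xlr5b, Gm15023 and Gm2913). Y-linked genes, 41 measured, had a median of 0.068 (adjusted p = 0.361), passed only without the library labelled control replicate 2 among the fits without a covariate (0.023, median 0.22), and turned to -0.028 by library totals and -0.22 with the covariate. In all, 17 of 22 sets passed with the preset correlation and 0 with an estimated one, and the count was 13 to 19 when 1 library was left out. By fry 0 sets passed (lowest adjusted p = 0.0659, spermatogonia).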

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

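The length percentile and the fit with a covariate were chosen only after the result was seen. The length that the deposited tables assign to L3mbtl2, a value outside the main measurement, was 3493 bases on average in the libraries labelled cKO and 2717 in those labelled control, a log2 ratio of 0.36. It drew attention because the length and the level of the targeted gene both separate the groups. The length did so in 17.1% of 2991 genes with several isoforms and like counts, and the level in 37.9% of all genes tested.

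L3mbtl2 was lower in every library labelled control than in every library labelled cKO. With the somatic marker score as a covariate the log2 fold change was 0.60 (SE 0.115, edgeR adjusted p = 0.669), more than 2 SE above 0. This cannot decide whether fewer germ cells in the libraries labelled control are the whole cause, since a count also depends on the length, which differed. On log2(FPKM + 1), scaled for length, the difference was 0.19 (limma adjusted p = 0.224). The pachytene list's median was 0.21 on that scale. A candidate explanation is that the genotype labels were exchanged between the groups, as the names of the deposited tables would have it. The length ratio lay above 99.9% of those of 2991 genes with several isoforms and like counts, whose central 95% ran from -0.13 to 0.082, but an altered allele under correct labels would change the length too. Exchanged labels and a deleted allele that yields more of an altered transcript therefore cannot be told apart here, since the tables give no exons.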

How the results depend on the processing

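The somatic score covariate was chosen after seeing the data. Over the alternatives, named genes other than L3mbtl2 kept direction and side in 528 of 569 comparisons and lists in 267 of 331. Of the rest, 30 and 3 newly passed, 0 and 32 no longer passed, and 11 and 29 changed sign. No named gene passed in the main fit, so that 0 was fixed in advance. For named genes, keeping side means only that they again did not pass. Where a value changed, the cause was not tested. These counts leave out the covariate for named genes and for the Sertoli and Leydig lists, which make the score and stood at 0.021 and 0.062 with it. The lymphocyte list had no value in the fits on FPKM or with the strict filter.

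DESeq2 called 72 genes higher and 1364 lower (22 and 828 at 2-fold), and L3mbtl2 at 0.69. limma on FPKM called 1 higher, also at 2-fold, with either pseudocount. Leaving out 1 library gave 0 to 2049 higher, 0 to 3851 lower, 0 to 97 and 0 to 2361 at 2-fold, and L3mbtl2 at 0.64 to 0.73. The highest counts come without the library labelled control replicate 2, which among those labelled control correlates best with the libraries labelled cKO. Other calls, named after their values were seen, were BGI_novel_G000333 and BGI_novel_G000591 (without control replicate 3), Hbb-bs, 1700084F23Rik and BGI_novel_G000829 (without cKO replicate 2) and LOC547349 (without cKO replicate 3), all higher. In simulated libraries of the same number and gene-wise dispersions edgeR recovered 54% of 2-fold and 95% of 4-fold changes. Genes were drawn there independently, with the same dispersion in both groups. The real libraries labelled control differed more from each other (pairwise correlations 0.937 to 0.972) than those labelled cKO (0.981 to 0.982). The simulation therefore cannot say whether the number of libraries accounts for the 0 calls. Library totals alone shifted the median of all genes to -0.10.

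An estimated correlation left 0 lists past the threshold, and X-linked genes at -0.45 (adjusted p 0.562). With the covariate 9 sets passed at the preset correlation, of which 1 (spermatogonia, -0.14) kept its sign and 8 had the opposite one, and 0 passed with an estimated correlation (lowest adjusted p 0.172). X-linked genes were at -0.046, elongating spermatids at 0.0086 and histone removal at 0.0056, none of them past the threshold. The covariate turned early meiotic (-0.15), pachytene (-0.039), round spermatid (-0.018), PRC1.6-bound (-0.17), piRNA (-0.11), flagellum (-0.029) and Y-linked (-0.22) lists negative, and myoid (0.22), macrophage (0.55), endothelial (0.12), blood (0.41), p53 (0.051), cholesterol (0.14) and interferon (0.30) lists positive. The 8 were the early meiotic, myoid, macrophage, PRC1.6-bound, piRNA, cholesterol, interferon and Y-linked sets. Of 37 named genes outside the score, 22 changed sign with it, 10 of them to positive, and 0 passed (lowest adjusted p 0.530): Cd74 went from -0.66 to 1.29, Lyz2 from -1.42 to 0.59 and Bst2 from -1.04 to 0.29. Of 4 named genes in the score, 2 changed sign, Insl3 to 0.29 and Clu to 0.088.

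Signs near 0 turned elsewhere. Blood cells gave 0.26 in DESeq2, 0.24 unfiltered, 0.047 with the strict filter and -0.055 to 0.44 with 1 library left out. Lymphocytes ran from -0.12 to 0.26 and Y-linked genes from -0.0061 to 0.22 with 1 library left out, the latter -0.028 by library totals. Egfl7 was -0.076 by totals, -0.11 and -0.14 on FPKM and ran from -0.15 to 0.23 with 1 library left out; by leaving out 1 library Cd74 ran from -1.02 to 0.068 and Hbb-b1 from -0.89 to 0.25.

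No sign was seen that replicate numbers pair libraries: same-number deviations correlated at 0.043, -0.0067 and -0.039, and control replicate 2 correlated better with cKO replicate 3 (0.074). So few libraries cannot exclude a pairing. The replicate block gave 0 genes, 17 lists, L3mbtl2 at 0.67 and Egfl7 at -0.0071.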

Other observations

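The tests chosen only after the result was seen were the fits with a somatic score covariate, the Leydig against Sertoli comparison, the epididymis count, the splits for edgeR, and the ontology terms. Genes in this part outside the fixed rule were chosen after their values were seen.

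Among the genes that DESeq2 called lower in the libraries labelled cKO, ontology terms from several fields were enriched. Of 2064 terms, 32 passed for the 1073 lower genes that carry a term, against a background of 12046, and 0 passed for the 32 higher genes by the same Fisher exact test. The lowest adjusted p was that of multi-organism reproductive process (17 of 42 genes, 7.6e-05). Others, picked after their values were seen, include response to estrogen (24 of 100 genes, adjusted p = 0.00359), steroid metabolic process (9 of 26, 0.0267), cell migration (39 of 215, 0.00397), phagocytosis (12 of 47, 0.0456), inflammatory response (22 of 119, 0.0478) and organelle inner membrane (40 of 223, 0.00397). The Leydig, Sertoli and macrophage lists were lower in these libraries too, and whether the terms follow cell composition was not tested. Gene by gene, the luteinizing hormone receptor Lhcgr, through which the pituitary drives Leydig cells, stood at 10.5 ± 7.07 FPKM in the libraries labelled control and 2.19 ± 0.602 in those labelled cKO (DESeq2 adjusted p = 0.00338). Igfbp3, an insulin-like growth factor binding protein, was at 6.94 ± 6.32 against 0.950 ± 0.161 FPKM (DESeq2 adjusted p = 0.00218). Among the higher genes, Peli2, a ubiquitin ligase of innate signalling, was at 38.0 ± 6.45 against 58.7 ± 5.35 FPKM (DESeq2 adjusted p = 0.00134). The ontology test rests on genes called by DESeq2 alone, since edgeR called 0 genes. In data simulated with the real dispersions DESeq2 gave 62 false calls, against 20 in edgeR. DESeq2 recovered 72% of 100 2-fold and 97% of 100 4-fold changes there. False calls thus made up more of its calls than the 0.05 threshold aims at, as they did in edgeR. These directions follow labels that L3mbtl2 leaves in doubt.

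The Sertoli and Leydig lists were higher and the spermatid lists lower in all 3 libraries labelled control than the mean of those labelled cKO, most of all in replicate 3, whereas the macrophage, myoid and endothelial lists stood well above that mean in replicates 1 and 3 alone. A uniformly lower share of germ cell RNA would change the Leydig and Sertoli lists alike if only somatic cells express them. The Leydig members had a mean log2 fold change of -1.84 ± 0.671 and the Sertoli members -0.99 ± 0.242 (SD, n = 18 and 25). The difference was -0.85 with a permutation p of 1e-05, the smallest that 100000 draws can give, over genes, which are not independent replicates. Without the library labelled control replicate 3 the difference was -0.53, with the same p. On that condition, which was not tested, the difference argues against such a share as the whole cause. Otherwise that cause stays open. Gene length bias is argued against too: with the length trend removed, the gap between the elongating spermatid and Leydig medians was 2.15, from 2.19 before. Epididymis dissected with the testis is argued against by its list, of which 1 gene of 15 (Rnase10) passed the count filter. A gain or activation of Leydig cells on top of a germ cell loss, a difference in dissection and an effect of genotype stay open, and which genotype depends on the labels.

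X-linked genes were lower in the libraries labelled cKO, and a candidate explanation is the share of somatic cells, in which the X chromosome is not silenced as it is in meiotic germ cells. With the somatic score as a covariate the X-linked median went from -0.45 to -0.046 (318 positive, 410 negative), as that explanation predicts. The score itself separates the groups, at 5.39 to 6.99 in the libraries labelled control and 4.90 to 5.01 in those labelled cKO. The covariate can therefore absorb a group difference of any cause, so this fit cannot tell the explanation from others. A difference in meiotic silencing beyond the somatic share was not tested.

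Where L3mbtl2 is lower, PRC1.6 may release its germline targets, so the list of genes it occupies in embryonic stem cells might be higher in the libraries labelled control once cell composition is taken into account. With the somatic score as a covariate the list's median was -0.17 and 0 of its 22 members were positive, but camera with an estimated correlation gave an adjusted p of 0.172. The piRNA list, which shares members with it, had a median of -0.11 with 0 of 17 positive (0.172 with an estimated correlation). The early meiotic list, of whose 24 genes 6 are also in another list, was at -0.15 (3 positive, 21 negative, adjusted p = 0.172 by the same camera test). Y-linked genes were at -0.22 (8 positive, 33 negative), but elongating spermatid genes at 0.0086 (12 positive, 10 negative). The shift was thus not particular to the PRC1.6-bound list. The score separates the groups, so these fits do not compare them at like composition and can absorb a group difference of any cause. Unshared members were not tested apart, and the hypothesis stays open.

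With a minimum count of 5, 8 features were read in all 3 libraries of one group and in none of the other. Of these, 4 were read only in the libraries labelled cKO (assembled models BGI_novel_G000437, BGI_novel_G001288, BGI_novel_G001917 and BGI_novel_G001940, the last with 233.91, 89.51 and 217.02 expected counts). The other 4 were read only in the libraries labelled control: Dusp28 on chromosome 1, with 35.83, 21.28 and 9.54, and the models BGI_novel_G000031, BGI_novel_G000993 and BGI_novel_G001944. Assembled models made up 7 of the 8 features, against 16.7% of 7868 features with like counts (odds ratio 35.1, Fisher exact p = 2.5e-05).

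The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In edgeR the split by label gave 0 genes (1617 higher and 3439 lower at an unadjusted p of 0.05, and 1436 by DESeq2) and the highest other split 1. Any split reaches a count of 0, so all 10 do by construction and that comparison tests nothing. DESeq2 gave 1436 genes against 41 in the highest other split (1 split as large, the split by label). For gene lists the split by label gave 17 and the highest other 19, with 4 splits as large. The other 3 of these put the libraries labelled control replicates 1 and 3 with 1 library labelled cKO, a structure of the libraries that follows the somatic score. For features read in 1 group alone it was 8 against 6, with 1 split as large.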
